A study of Mus musculus with 2 samples.

How the data were processed

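Chromatin carrying histone H3 trimethylated at lysine 9 (H3K9me3), a mark of repressed chromatin, was immunoprecipitated from the facial prominence of mouse embryos at 13.5 days and sequenced. Per the labels, tissue came from healthy B6NCrl embryos of both sexes, pooled, and the 2 samples are biological replicates 1 and 2 of 1 group. The labels give a size range of 300 to 500 and the mm10 assembly. No treatment, genotype or second tissue was part of the series, so the only comparison between samples is replicate against replicate.

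The authors deposited 4 peak lists on mm10 in the narrowPeak format. Per the text files deposited with the samples, one list was made from the alignments of replicate 1 and a control file, one from those of replicate 2 and another control file, and a pooled list from both alignments and both control files. The replicated list was derived from those 3 lists. The aligner, peak caller, their versions and the rule of the replicated list are not given in the sources used here. For each peak the authors deposited a fold enrichment over control as a linear ratio. The authors also deposited the −log10 of a p-value and the −log10 of a q-value for each peak. A display score that the authors deposited for each peak was read and not used in any test. The offset of the summit from the peak start came from the same lists. These values belong to the authors' peaks and were used to describe, rank or filter peaks within a list. The lowest −log10 p in each list lies just above 2, so the lists hold many weak calls. Read counts are not part of the peak lists, so the depth of the samples is unknown and no value below carries an error from depth. Intervals of shares are exact Clopper-Pearson intervals at 95% and cover counting error only. Peaks and genes are not independent replicates, and p-values from placements along the chromosomes or from random gene lists describe these 2 samples, not a wider set of embryos.

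Peak positions were set on the GRCm38 assembly (patch 6), the same build as mm10. The lengths of the 21 assembled chromosomes were checked against the annotation, and no peak ran past a chromosome end. Gene models were the protein-coding and long non-coding RNA genes of the GENCODE mouse release M21 (21938 and 10155 genes on the assembled chromosomes). For each gene the transcript with the longest coding sequence gave the transcription start site (TSS) and the last exon. Overlapping gene models, as in the clustered protocadherin and Ugt1a loci, share peaks and were each counted. Peaks on unplaced scaffolds were counted in the lists and left out of tests that use chromosomes or genes.

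All calculations used Python 3.11.15 with NumPy 2.4.6, pandas 2.3.3 and SciPy 1.17.1, matplotlib 3.10.9 for the figures, and BLAST+ 2.17.0 for the identity of the last exons of zinc finger genes. Peaks of the replicates were called shared when they overlapped by at least 1 bp. The share was compared with 1000 circular shifts of the other replicate's peaks along each chromosome, which keep the spacing of peaks (one-sided, smallest possible p of 0.000999). The replicated list was the main list for all other results, with each replicate's own list beside it. Summits were assigned to promoters (1000 bp on either side of a TSS of any transcript), then exons, then introns, then intergenic sequence. The shares, and the GC, CpG and soft-masked repeat content of the peaks, were compared with 1000 circular shifts (two-sided, smallest possible p of 0.002). For 19 gene lists, the number of genes with a replicated peak over the gene body was compared with 10000 random lists of the same size, matched on biotype and on 10 classes of gene length (two-sided, smallest possible p of 0.0002), with Benjamini-Hochberg adjustment over the 19 lists. Of the listed names, Ahsp was not found in the annotation and 2 names of the H3K9 machinery list (Fam208a and Tasor) are the same gene. Rpl10l is a member of both the ribosomal protein and the germline list. The comparisons with circular shifts and with random lists are permutation tests, of peak positions and of gene labels. Peaks over the last exon and at the TSS were compared by an exact McNemar test over genes. Replicated peaks closer than 10000 bp were joined into domains. On simulated data, 1% of 200 random lists of 50 genes were called at an unadjusted p under 0.05, and 100% of 200 lists with 15 planted genes were called. Simulated independent peak lists overlapped 0.997 times as often as their shifts. The simulated peaks lay at uniformly random positions and the simulated lists held random genes. These rates therefore do not cover clustered peaks or tandem gene families.

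The gene lists, the tests described above and their alternatives were fixed before the data were examined. Tests of explanations for single patterns were chosen later. The rule for named genes was also fixed in advance: the 15 protein-coding genes of at least 2000 bp with the largest share of the body covered by replicated peaks and a peak in both replicates; the 4 genes of each list with the largest covered share; the genes nearest to the 10 peaks of highest fold enrichment; up to 3 genes in each of the 10 domains with the most covered sequence; and up to 10 imprinted, germline and facial development genes with a replicated peak within 1000 bp of the TSS. Genes named outside this rule are marked as chosen after their values were seen. Alternatives were a −log10 q of at least 2, the list of each replicate alone, other rules of overlap, other random controls, a promoter of 2000 bp upstream to 500 bp downstream, at least 500 bp of the gene body, and joining distances of 5000 and 20000 bp. Restricting the replicated list to peaks that overlapped a peak of each replicate by 50% of either peak was added after seeing the data.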

Results

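H3K9me3 was profiled by ChIP-seq in the facial prominence, the embryonic tissue that forms the face and jaws, of mouse embryos at 13.5 days. The series held 1 group of 2 biological replicates. Read totals are not part of the peak lists, so the depth is unknown. Positions are on mm10 and count from 1. The authors called 60388 peaks in replicate 1 and 59138 peaks in replicate 2, which covered 16.5 Mb and 16.7 Mb. Peaks were short, with a median width of 220 bp and 227 bp, and the median fold enrichment over control was 3.15 and 3.10. The pooled list held 74106 peaks. The replicated list held 24762 peaks, with a median width of 393 bp and a median fold enrichment of 3.44, and covered 12.1 Mb with the unplaced scaffolds included. Its peaks on assembled chromosomes covered 0.435% of their sequence. In this list 88.8% of peaks had a −log10 q of at least 2, against 53.7% in the pooled list, which holds all of its peaks. The share was 24.3% in replicate 1 and 25.4% in replicate 2, in lists made from 1 replicate each.

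The replicates were compared first, since no other contrast was part of the design. The strongest peaks of each replicate mostly overlapped a peak of some strength in the other, and the weakest mostly did not. Of the peaks of replicate 1, 18640 (30.9%, 95% interval 30.5% to 31.2%) overlapped a peak of replicate 2, and of the peaks of replicate 2, 18513 (31.3%, 95% interval 30.9% to 31.7%) overlapped a peak of replicate 1. On the assembled chromosomes the circular shifts gave 1.39% ± 0.136 (SD over shifts) and 1.42% ± 0.142, so that the overlap was 21.9-fold above the shifts in both directions (permutation p = 0.000999, the smallest that 1000 shifts can give). Among the strongest 10% by −log10 p, 68.2% of replicate 1 peaks and 70.1% of replicate 2 peaks were shared, and among the weakest 10%, 16.4% and 17.4%. These shares are against the whole list of the other replicate. When strong peaks were set against strong peaks, most were not shared: 31.5% and 31.3% of the 10000 strongest, and 30.8% and 29.9% of those with a −log10 q of at least 2, overlapped one of the same class. The share of all peaks also fell with stricter overlap, to 21.2% and 20.7% at 50% of the peak and to 15.8% and 16.1% at reciprocal 50%. Many peaks tie in −log10 p, and ties were ordered by position. By length, 16.0% of the sequence covered in either replicate was covered in both. Across the 18640 pairs of shared peaks the fold enrichment of the replicates had a Spearman correlation of 0.198. This describes peaks, which are not independent replicates.

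**Figure D1:**
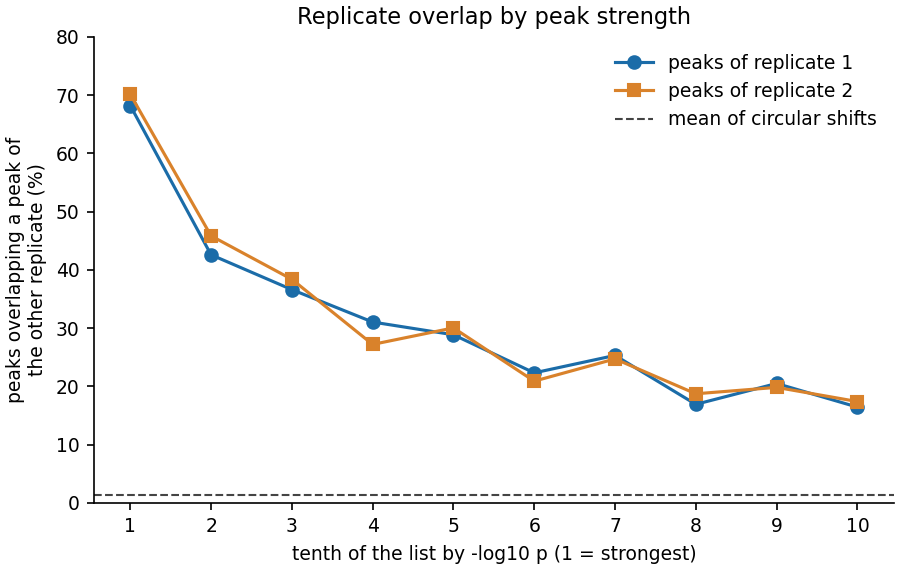
Share of peaks (%) of replicate 1 (circles) and replicate 2 (squares) that overlap a peak of the other replicate by at least 1 bp, in 10 steps of each list ranked by −log10 p, with the mean of circular shifts as a dashed line. The share falls from 68.2% and 70.1% in the strongest step to 16.4% and 17.4% in the weakest, above the shifts in each step.

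All 24762 replicated peaks were also peaks of the pooled list. A peak of each replicate covered at least 50% of the peak in 10228 of them (41.3%). Counting an overlap of 50% of either peak, a rule chosen after seeing the data, 16922 (68.3%) had a peak in each replicate, and all 16922 pooled peaks that met this rule were in the replicated list. The other 7840 replicated peaks (31.7%) did not meet it, and 346 (1.40%) met it in neither replicate. The replicated list is therefore wider than the set of peaks called in each replicate.

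The mark was unevenly spread over the chromosomes, and chromosomes 7, 17, 13 and 4 led in this order in both replicates. Chromosome 7 carried the most, with 11.1 kb of replicated peaks per Mb against 4.35 kb per Mb over all assembled chromosomes, a ratio of 2.56. Its coverage was 13.5 kb per Mb in replicate 1 and 12.8 kb per Mb in replicate 2. Chromosome 17 followed with 8.56 kb per Mb, a ratio of 1.97. Chromosomes 13, 4, 18 and 5 had ratios of 1.42, 1.40, 1.36 and 1.27. Little peak sequence was called on the sex chromosomes, with 0.820 kb per Mb on chromosome X, a ratio of 0.188, and 0.0896 kb per Mb on chromosome Y, a ratio of 0.0206. These values are per full chromosome length. Copy number of the sex chromosomes in the pools and the sequence on which reads can be placed were not taken into account. Low coverage there need not mean that the mark is absent. Chromosome X differed between the replicates, with 980 peaks in replicate 1 and 1478 in replicate 2, and its ratio rose to 0.361 in the list of replicate 2 alone. With 1 group of 2 samples, no test of this difference against biological spread was possible.

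**Figure D2:**
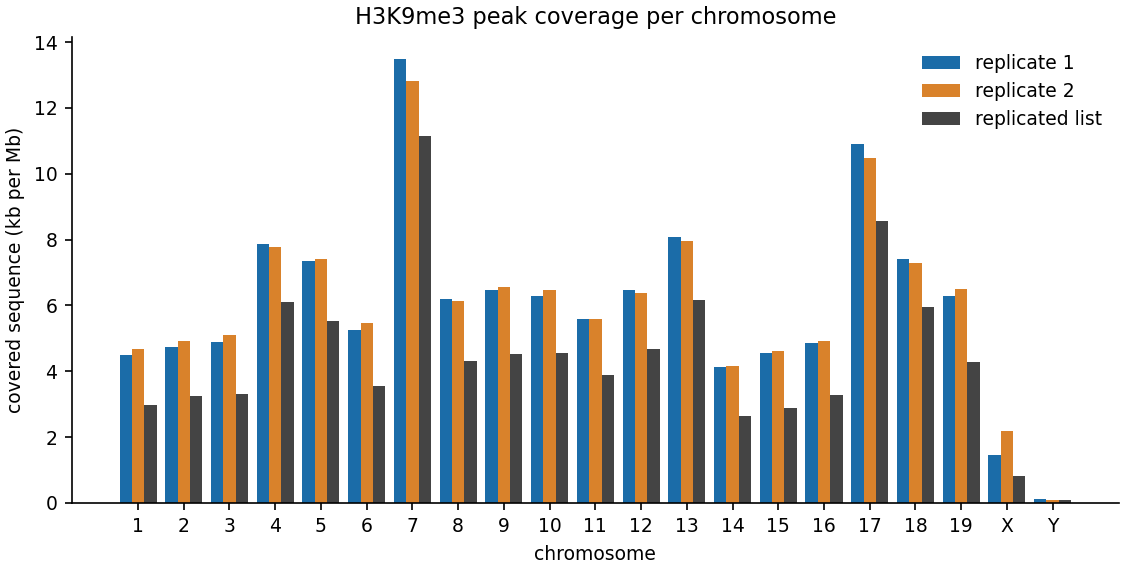
Sequence covered by H3K9me3 peaks (kb per Mb) on each chromosome in replicate 1, replicate 2 and the replicated list. Chromosome 7 stands highest at 13.5, 12.8 and 11.1 kb per Mb, and chromosomes X and Y stand lowest.

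Where the peaks lay against genes was compared with circular shifts. Replicated summits fell between genes and in exons more often, and in introns less often, than shifted summits. Of 24518 summits on assembled chromosomes, 59.7% were intergenic against 51.8% ± 1.29 (SD over shifts), 33.5% intronic against 42.3% ± 1.22 and 4.11% exonic against 2.97% ± 0.183 (each permutation p = 0.002, the smallest that 1000 two-sided shifts can give). Promoters held 2.72% of summits against 2.97% ± 0.205, which did not pass the threshold (permutation p = 0.23), although the list of replicate 2 alone gave 2.47% against 2.90% (permutation p = 0.002). The peaks were richer in G and C, with 45.8% against 42.1% ± 0.233 (permutation p = 0.002). Soft-masked repeat sequence made up 33.3% of peak sequence and 33.8% ± 0.634 of shifted sequence (permutation p = 0.41). The shifts could fall on repeats where reads may not be placeable, so these shares do not settle whether repeats carried the mark more often. The ratio of observed to expected CpG was 0.190 against 0.194 ± 0.00255 (permutation p = 0.15), but in the list of each replicate alone it lay below the shifts, at 0.183 against 0.193 (permutation p = 0.002 for both).

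Over all genes, 3644 of 21938 protein-coding genes (16.6%) and 1065 of 10155 long non-coding RNA genes (10.5%) carried a replicated peak in the gene body. Protein-coding promoters carried one in 376 genes (1.71%). Of the 19 gene lists, 5 carried replicated peaks more often than length-matched random genes, and none less often. They were zinc finger genes, vomeronasal receptors, clustered protocadherins, imprinted genes and germline genes.

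**Figure D3:**
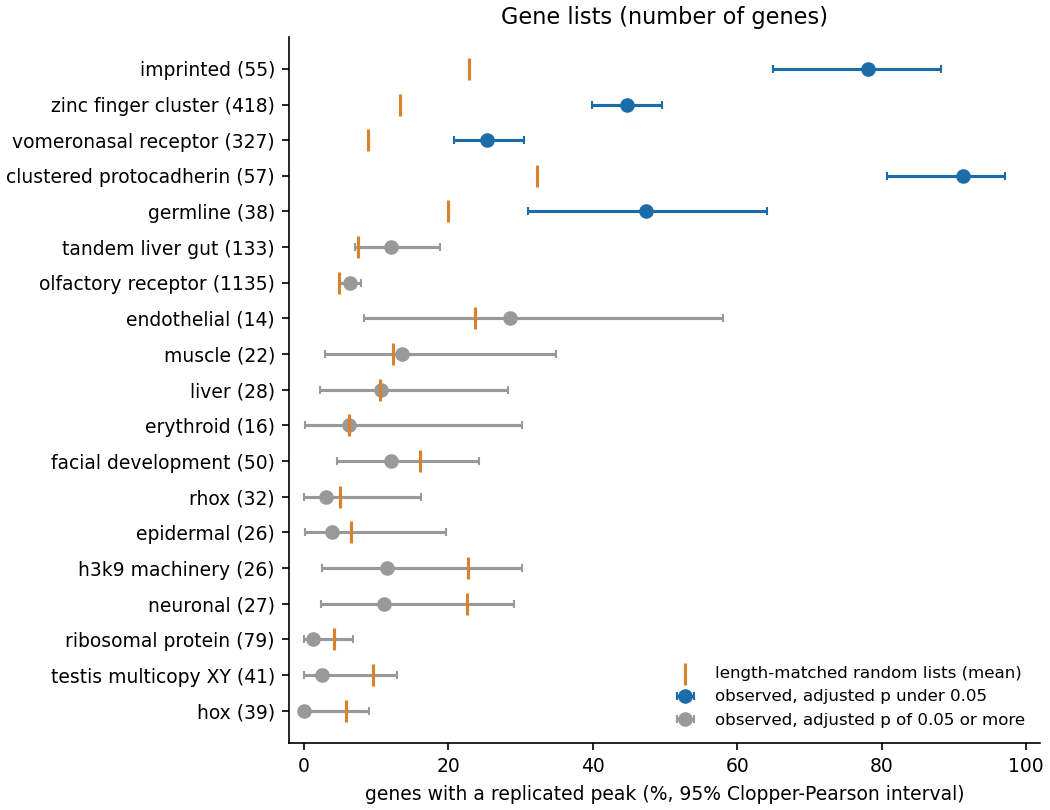
Share of genes (%) with a replicated H3K9me3 peak in each of the 19 gene lists, as points with 95% Clopper-Pearson intervals, and the mean of 10000 length-matched random lists as upright marks. In 5 lists, drawn in blue, the share exceeds the random lists at an adjusted p under 0.05, from 25.4% in vomeronasal receptors to 91.2% in clustered protocadherins.

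Zinc finger genes, many of which encode KRAB zinc finger repressors and lie in tandem arrays, carried the mark more often than matched genes, and more often over the last exon than at the TSS. Of 418 genes, 187 (44.7%, 95% interval 39.9% to 49.6%) had a replicated peak against 13.4% in matched lists, a ratio of 3.35 (adjusted permutation p = 0.00095). Replicates 1 and 2 alone marked 241 and 236 of them, with lower ratios of 2.16 and 2.23 (adjusted permutation p = 0.00076 for both). Zfp110 on chromosome 7 (12834761 to 12850577) was covered over 87.9% of its 15.8 kb in the replicated list, 79.6% in replicate 1 and 75.7% in replicate 2. Zfp873 was covered over 87.7%, Zfp146 over 78.2% and Zfp68 over 76.4%. These were the most covered genes of the list. Among its genes with a replicated peak the median covered share was 8.51%. A peak lay over the last exon, which in this class usually encodes the zinc fingers, in 133 genes (31.8%) and within 1000 bp of the TSS in 18 genes (4.31%). The share at the TSS was itself above the 1.53% in matched lists, a ratio of 2.82 (adjusted permutation p = 0.00152). The last exon alone was marked in 121 genes and the TSS alone in 6 (exact McNemar test, two-sided, p = 6.4e-29). The median last exon of the zinc finger genes was 2488 bp, against 1100 bp in other protein-coding genes, so it also offered more sequence. In the other 21520 protein-coding genes the shares were 1.92% and 1.66% (exact McNemar test, p = 0.0166), a difference that turned round with a promoter of 2000 bp upstream to 500 bp downstream (exact McNemar test, p = 0.0441). It was not past the threshold in the list of replicate 2 alone (exact p = 0.0976) or of replicate 1 alone (exact p = 0.413).

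Clustered protocadherins, cell adhesion proteins of neurons encoded in 3 neighbouring arrays on chromosome 18, were the list with the largest marked share. Of 57 genes, 52 (91.2%, 95% interval 80.7% to 97.1%) had a replicated peak against 32.2% in matched lists (ratio 2.83, adjusted permutation p = 0.00095). In 43 genes (75.4%) a peak lay within 1000 bp of the TSS against 1.84% in matched lists, a ratio of 40.9 (adjusted permutation p = 0.00095). The region from 36930184 to 37841873 held 423 peaks in replicate 1, 399 in replicate 2 and 282 replicated peaks, which covered 194.1, 190.9 and 213.7 kb of it. The most covered genes were Pcdhb15, at 89.6% of the body, Pcdhb22 at 67.7%, Pcdhb17 at 61.1% and Pcdhb21 at 57%. Pcdhb15 was covered over 73.7% in replicate 1 and 37.8% in replicate 2. The domain with the most covered sequence in the genome lay over the starts of the Pcdhga and Pcdhgb genes of the gamma array (37655803 to 37781586), where 74 peaks covered 96.9 kb, or 77.0%. It did not reach the 3 Pcdhgc genes. Gene models of the gamma and alpha arrays overlap and share peaks, so their counts are not independent. In the lists of single replicates, which are longer, the ratio was 1.93 and 2.00 with the adjusted permutation p still under 0.001.

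**Figure D4:**
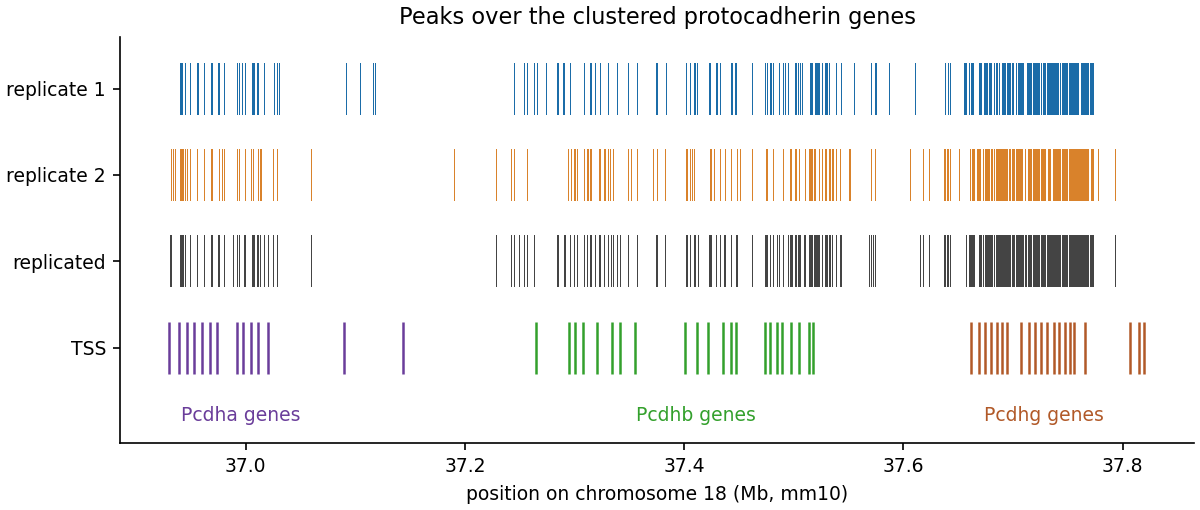
Map of the clustered protocadherin genes on chromosome 18 (mm10, position in Mb), with the peaks of replicate 1, replicate 2 and the replicated list as bars drawn to scale and the TSS of each gene as a line. Peaks crowd over the Pcdhga and Pcdhgb genes, where 74 replicated peaks cover 77.0% of the domain from 37655803 to 37781586.

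Imprinted genes, expressed from the copy of 1 parent, carried the mark in 43 of 55 cases (78.2%, 95% interval 65.0% to 88.2%) against 22.9% in matched lists, with a ratio of 3.41 (adjusted permutation p = 0.00095). In 20 genes (36.4%) a peak lay within 1000 bp of the TSS against 1.77% in matched lists, a ratio of 20.5 (adjusted permutation p = 0.00095). The highest fold enrichment at a TSS was 7.49 at Plagl1 (peak 13090043 to 13091589 on chromosome 10), a zinc finger transcription factor. Cdkn1c, an inhibitor of the cell cycle, followed with 7.30, and its gene body was covered over 79.4%. Impact and Zrsr1 each had 7.11. Peg3 and Usp29, neighbours on chromosome 7, shared a peak of 7.10 (6727242 to 6731253). Gnas, which encodes a G protein subunit, had 6.74, Mest had 6.36, Peg13 had 5.68 and Nap1l5 had 5.62. All 10 had peaks at the TSS in both replicates. Nnat had the largest covered share of the list, at 87.9% of the gene body. With the list of replicate 1 alone the ratio was 1.98, with an adjusted permutation p of 0.00076.

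Germline genes, which act in egg and sperm precursors and are silent in most somatic cells, carried a replicated peak in 18 of 38 cases (47.4%, 95% interval 31.0% to 64.2%) against 20.0% in matched lists, a ratio of 2.37 (adjusted permutation p = 0.00152). A peak lay within 1000 bp of the TSS in 13 genes (34.2%) against 1.60% in matched lists, a ratio of 21.4 (adjusted permutation p = 0.00095), and over the last exon in 1. Dazl, an RNA-binding protein of germ cells, had the highest fold enrichment at its TSS with 5.24 (50293223 to 50294255 on chromosome 17). Ddx4, a germ cell RNA helicase, had 4.87, and Taf7l and Meioc had 4.49. Stag3, a meiotic cohesin subunit, had 3.91, and Stk31, Smc1b and Brdt each had 3.74. Fkbp6 had 3.70 and Sycp2 had 3.56. In 8 of these 10 genes a peak lay at the TSS in each replicate. Brdt lacked one in replicate 2 and Sycp2 in replicate 1. The ratio fell to 1.48 with the list of replicate 1 alone, with an adjusted permutation p of 0.0394.

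Vomeronasal receptors, which sense pheromones in the nose, carried a peak in 83 of 327 genes (25.4%, 95% interval 20.8% to 30.5%) against 8.88% in matched lists, a ratio of 2.86 (adjusted permutation p = 0.00095). The most covered were Vmn1r65 at 29.0%, Vmn1r70 at 27.4%, Vmn1r82 at 24.9% and Vmn1r71 at 22% of the gene body, all on chromosome 7. The ratio was 1.95 in the list of each replicate alone, with the adjusted permutation p still under 0.001. Olfactory receptors, the larger family of odour receptors, had a peak in 72 of 1135 genes (6.34% against 4.89%, ratio 1.30), which did not pass after adjustment (permutation p = 0.02, adjusted permutation p = 0.063). In the lists of single replicates they passed against random genes, with ratios of 1.53 without replicate 1 and 1.49 without replicate 2 (adjusted permutation p = 0.00076 for both). Random genes do not keep the spacing of tandem arrays. Against circular shifts of the replicated list the ratio was 1.09 (unadjusted permutation p = 0.695). With at least 500 bp of the gene body it was 1.07 (unadjusted permutation p = 0.74). Olfr356 was covered over 76.9%, with 21.4% in replicate 1 and 61.4% in replicate 2. The tandem liver, gland and gut families had peaks in 16 of 133 genes (ratio 1.59, adjusted permutation p = 0.21), led by Defb33 at 21.2%. They passed only in the lists of single replicates, with ratios of 1.64 and 1.55. Their ratio against circular shifts of the replicated list was 1.42 (unadjusted permutation p = 0.30).

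The list of facial development genes and the lists of genes of other cell types did not pass the test against matched genes. Among transcription factors and signals of facial development, 6 of 50 carried a peak (12%, ratio 0.746, adjusted permutation p = 0.74). None had one within 1000 bp of the TSS, against only 1.73% in matched lists (unadjusted permutation p = 0.82). That absence is therefore no sign that the mark avoids these promoters. The 4 most covered were Six4 at 2.51% of the gene body, Wnt3 at 1.83%, Twist2 at 0.711% and Runx2 at 0.439%, and Pax7 and Trp63, chosen after their values were seen, were the other 2. None of 39 Hox genes carried a replicated peak, against 5.80% in matched lists (adjusted permutation p = 0.35), and the upper end of the 95% interval was 9.03%. In the lists of single replicates 3 Hox genes had a peak in replicate 1 and 5 in replicate 2, 1 of them in both, and the ratio turned to 1.13 in replicate 2 alone (adjusted permutation p = 1). The single gene among 79 ribosomal protein genes was Rpl10l, a testis gene with no peak in replicate 2 (adjusted permutation p = 0.49). Replicated peaks lay in 3 of 27 neuronal genes (Rbfox3, Syt1 and Nrxn1, adjusted permutation p = 0.34), 3 of 22 muscle genes (Ttn, Ckm and Neb, adjusted permutation p = 1), 4 of 14 endothelial genes (Pecam1, Tek, Flt1 and Erg, adjusted permutation p = 1) and 3 of 28 liver genes (Ambp, Cyp3a11 and Cps1, adjusted permutation p = 1). One gene each was marked among 16 erythroid genes (Epb42) and 26 epidermal genes (Flg2), both with an adjusted permutation p of 1. Among 26 genes for H3K9 methylation and its readers, Atf7ip, Setdb1 and Morc2a carried a peak (adjusted permutation p = 0.35). Rhox13 was the marked gene of 32 Rhox genes (adjusted permutation p = 1) and Ssxb10 that of 41 multicopy testis genes of the sex chromosomes (ratio 0.253, adjusted permutation p = 0.28), a list that passed in the list of replicate 1 alone (ratio 0.263, adjusted permutation p = 0.0255). Against circular shifts, which keep the low density of the sex chromosomes, its ratio was 0.785 (adjusted permutation p = 1). Ckm and Ssxb10 had no peak in the list of replicate 1.

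Among single genes, the strongest peak by fold enrichment lay on Klf14, a transcription factor gene with 1 coding exon. The peak (chromosome 6, 30956173 to 30959246) had a fold enrichment of 15.9, with 13.5 and 14.6 in replicates 1 and 2, and replicated peaks covered 96.9% of the gene. The next lay in an exon of Asmt, the last enzyme of melatonin synthesis, on chromosome X (170674184 to 170675299) with 11.2. An intergenic peak on chromosome Y (259036 to 259459) had 11. Exonic peaks followed at Zfp810 with 10.3, Gm44973 with 9.73, and Zfp513 and Gm45021 with 9.55 each. An intergenic peak 4.43 kb from Vmn1r238 had 9.62. A peak in the protocadherin gamma array had 9.41, and one 22.6 kb from Vmn1r77 had 9.39. Besides genes already named, the protein-coding genes of at least 2000 bp with the largest covered share were Gm21738 at 100%, Ugt1a1, the bilirubin-conjugating enzyme, at 92.3%, Scgb2b24 at 90.4%, Mroh2a at 87.2%, Obox8 at 81.3% and Il3ra, an interleukin receptor subunit, at 78.1%. The peak over Gm21738 had a fold enrichment of 2.32, below the median of 3.44 over the replicated list. In replicates 1 and 2, Ugt1a1 was covered over 90.7% and 89.5%.

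Joining replicated peaks closer than 10000 bp gave 14286 domains, of which 10836 were single peaks. The 225 domains with 10 or more peaks held 18.5% of the peaks. Both values depended on the joining distance, with 138 such domains and 9.47% of the peaks at 5000 bp and 244 domains and 27.9% at 20000 bp. The lists of replicates 1 and 2 alone, which are longer, gave 463 and 443 such domains. After the gamma protocadherin domain, the domains with the most covered sequence lay at Vmn1r75 and Vmn1r76 on chromosome 7 (11856516 to 12031666, 49.8 kb covered), at the beta protocadherins (37402024 to 37543737 on chromosome 18, 49.0 kb) and at Ugt1a and Mroh2a on chromosome 1 (88204139 to 88265699, 46.0 kb). Further domains lay at Ceacam12 on chromosome 7 (44.8 kb), at Zfp369 on chromosome 13 (41.6 kb), at AU041133 on chromosome 10 (34.3 kb) and at Zfp942 and Zfp943 on chromosome 17 (34.1 kb). The remaining pair, on chromosome 3 (3000073 to 3079938, 37.2 kb) and chromosome 4 (121975390 to 122059469, 34.8 kb), overlapped no protein-coding gene. In each of the 10, both replicates covered at least 25.6 kb. The lists of single replicates gave 32073 domains without replicate 1 and 32367 without replicate 2.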

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

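Of 211 values under alternatives for 36 results, 169 counted as unchanged. For tests this meant the same direction and the same side of the threshold, also where the main result had not passed. For values without a test it meant lying within a set margin of the main value. Of the others, 22 changed direction, 9 newly passed the threshold, 1 no longer passed and 10 moved beyond the margin. All alternatives were chosen before the data were examined except 50% of either peak and 50% overlap with a peak of each replicate. The overlap of the replicates stayed above the shifts in all of its alternatives, although the share fell to 21.2% and 20.7% at 50% of the peak and to 15.8% and 16.1% at reciprocal 50%, and the excess at the last exon of zinc finger genes kept its direction and its call in all of its own. The 5 gene lists past the threshold passed in all 7 alternatives each, with the highest adjusted p at 0.0486 for germline genes. The rank correlation moved to 0.268 with −log10 p and 0.287 with reciprocal 50% overlap. The share of replicated peaks with a peak in each replicate moved to 69.4% at 1 bp and 68.3% at 50% of either peak. Without one replicate, where the longer list of the other replaces the replicated list, the ratio of chromosome 7 ranged from 2.13 to 2.26, that of chromosome X from 0.245 to 0.361, the number of gene lists past the threshold from 7 to 8, and the number of domains from 32073 to 32367. Also without one replicate, the ratio of olfactory receptors ranged from 1.49 to 1.53, of tandem liver and gut families from 1.55 to 1.64, of multicopy testis genes from 0.263 to 0.407, of promoter summits from 0.852 to 0.936 and the CpG ratio of peaks from 0.183 to 0.183, below the shifts for both (permutation p = 0.002). With 50% overlap with a peak of each replicate, the repeat share was 32.6%, below the shifts (permutation p = 0.042), and the CpG ratio 0.198 turned above them (permutation p = 0.16). The difference between last exon and promoter in other protein-coding genes ranged from -0.135 to 0.256 percentage points without one replicate and turned to -0.242 with the promoter of 2000 bp upstream to 500 bp downstream. The causes were not tested. In 9 lists that did not pass, the ratio changed sides of 1 in 19 alternatives, none past the threshold (lowest adjusted p 0.353). With promoters these were 1.5 for Rhox, 0 for muscle, 2.12 for neuronal, 0 for erythroid, 0 for endothelial and 5.21 for H3K9 machinery genes. With circular shifts they were 3.16 for Rhox, 0.958 for muscle and 0.918 for liver genes. With 50% overlap with a peak of each replicate they were 0.925 for muscle and 0.753 for endothelial genes. With 500 bp of the gene body they were 0 for erythroid and 1.08 for epidermal genes, and with a −log10 q of at least 2, 0.736 for liver genes. Without one replicate the ranges were 0.637 to 1.13 for Hox, 0.945 to 1.02 for erythroid, 0.723 to 1.42 for endothelial, 0.975 to 1.01 for liver and 0.600 to 1.40 for epidermal genes. No paired analysis was possible because the series holds 1 group. Depth is unknown, which limits all statements on missing peaks.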

Other observations

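Of the tests below, those on weak calls on chromosome X and on unplaced scaffolds were chosen after the result was seen. The test of −log10 p on chromosome X was added after the test of fold enrichment. The comparison of the gene lists with circular shifts was fixed before the data were examined. Its use as a test of tandem clustering was chosen after the result was seen. Large domains of the mark held a mixed set of gene families. Of the 225 domains with 10 or more replicated peaks, 37 (16.4%) overlapped a zinc finger gene of the fixed list, 20 (8.89%) a vomeronasal receptor, 8 (3.56%) an olfactory receptor and 5 (2.22%) a clustered protocadherin. A further 90 (40.0%) overlapped no protein-coding gene. None overlapped a gene of the germline, facial development or Hox lists, nor of several others such as the ribosomal protein, neuronal and liver lists. The germline, facial development and Hox lists hold 38, 50 and 39 genes, against 418 zinc finger genes and 1135 olfactory receptors. The overlaps are counts with no test and no expected value, so a lack of overlap does not show avoidance.

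Endogenous retroviruses prime their reverse transcription with a cellular tRNA, so matches to the 3′ ends of tRNAs mark candidate proviral sites. The 403 annotated tRNA genes gave 55 distinct sites of 18 bases with 2627 matches in the assembly. The hypothesis was that replicated peaks lie near such sites, set against placement without regard to them. A peak lay within 1000 bp of 31.6% of 174 tRNA-Pro sites, 19.4-fold above circular shifts, of 26.1% of 176 tRNA-Lys sites (12.6-fold), of 10.5% of 1090 tRNA-Phe or tRNA-Ser sites (5.23-fold) and of 9.09% of 154 tRNA-Gln sites (4.43-fold). Each of these exceeded all 1000 shifts (adjusted permutation p = 0.003). Sites of tRNA-Gly (4.22%, 2.46-fold, adjusted permutation p = 0.0144) and tRNA-Ile (3.22%, 1.60-fold, adjusted permutation p = 0.04) passed the threshold but stayed under the highest shift. Placement without regard to the sites is therefore unlikely for the first 4 groups. The excess was weaker for tRNA-Gly and tRNA-Ile. The soft-masked share of the peaks did not exceed the shifts, but these could fall on repeats where reads may not be placeable. Whether a match belongs to a provirus, and how many sites could be covered by uniquely placed reads, was not tested.

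The excess of peaks at zinc finger genes, vomeronasal receptors and protocadherins could come from counting 1 marked region once for each gene of a tandem array. Circular shifts keep the spacing of genes and peaks, and the highest adjusted permutation p of the 3 lists under them was 0.0152. For zinc finger genes and vomeronasal receptors this argues against clustering as the whole source, although their ratios were lower (2.64 and 1.97). The 57 protocadherins lie in 1 region of chromosome 18, counted once for each gene. For them the shifts ask only whether this region is marked beyond other places on the chromosome, so they cannot decide. Reads shared between close paralogs were tested on the zinc finger genes. The 209 genes whose closest other member had a last-exon identity of at most 73.3%, 78 of them with no match at all, still carried peaks 2.95-fold above matched genes (permutation p = 0.0002, the smallest that 10000 lists can give), and the 209 more similar genes 3.75-fold. Identity was searched only among the last exons of this list, while peaks were counted over the whole gene body. Of the 209 less similar genes, 58 had a peak over the last exon. Shared reads elsewhere in a gene, or with copies outside the list, are therefore not excluded. With 1 tissue and 1 group, no biological explanation was tested.

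Replicate 2 had more peaks on chromosome X than replicate 1, with an odds ratio against the autosomes of 1.55 (95% interval 1.43 to 1.69, counting error only). Among peaks with a −log10 q of at least 2 the ratio was 1.12 (0.922 to 1.37), so the excess lay mostly among weaker calls. By sharing, the odds ratio was 0.990 (0.828 to 1.18) among shared peaks and 1.75 (1.60 to 1.92) among peaks not shared. A shared peak pairs with a peak of the other replicate on the same chromosome, so a ratio near 1 was built in. Any excess had to lie among peaks not shared, so this split adds no evidence. At the 245 shared peaks of chromosome X, the log2 ratio of fold enrichment between replicates 2 and 1 differed from that on the autosomes by -0.013 (95% bootstrap interval -0.069 to 0.015). Unequal depth of ChIP and control on this chromosome was predicted to shift it. The same difference for −log10 p was -0.041 (-0.196 to -0.020), below 0, where a higher depth in both the ChIP and the control of replicate 2 would put it above 0. Shared peaks leave out peaks that a depth difference would add to 1 replicate, so neither value decides on depth. Why weaker calls on chromosome X were more frequent in replicate 2 stays open, and the make-up of the pools by sex is not given in the sources used here.

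Many of the peaks with the highest −log10 p had a moderate fold enrichment, with a median of 4.15 over the 20 highest, although the peaks on chromosome Y and near Vmn1r238 that stood out by fold enrichment were among these 20. Of the 20, 9 lay on unplaced scaffolds, and others lay at Sfi1 and Drg1 on chromosome 11 (3190958 to 3197224, −log10 p 179.6, fold enrichment 4.15) and at Gm26917 on chromosome 17 (39842973 to 39846776, −log10 p 120.3, fold enrichment 2.96), chosen after their values were seen. Sequence present in more copies than the assembly holds would give deep coverage in ChIP and control alike, and so a high −log10 p at a low fold enrichment. Among peaks with a −log10 p of at least 30, the 59 on scaffolds had a median fold enrichment of 4.06 and the 96 on assembled chromosomes 5.47, a difference of -1.41 (two-sided permutation test over peaks, 100000 permutations, p = 0.00064), as that candidate explanation would give. Their median −log10 p also differed, at 46.1 and 39.5. The compared peaks include the 20 that prompted the test, so it is not independent support. Peaks of the same scaffold were permuted as if independent, and most of the 9 lay on scaffold JH584304, so the p-value is too small. The depth itself is unknown, and no biological explanation was tested.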
